A study of Sus scrofa with 22 samples.

How the data were processed

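Jejunal mucosa RNA from 22 pigs was measured by RNA sequencing. Per the labels' protocols, RNA with a quality indicator above 8 was made into TruSeq version 2 libraries and sequenced on a NextSeq instrument as single reads of 150 bases, and the reads were processed in a CLC workbench against the annotated pig genome Sscrofa11.1. The deposited values are counts of unique exon reads per gene, per the file headers, with 24358 genes in each library. The version of the workbench and its mapping settings are not given in the sources used here. Reads that match several places equally are absent from unique counts, so genes with near-identical copies, such as FOLH1B, IFITM3 and the SLA genes, are uncertain.

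Groups were taken from the diet label of each sample. The series text ties an abbreviation to the Western pattern without drug that the sample titles use for the Western pattern with drug, and the sample labels were followed. Of the gene identifiers, 17332 were named in the files and 1050 more through a table of gene names, and 5976 stayed unnamed. Coordinates of named genes were taken from the RefSeq annotation of Sscrofa11.1 by symbol. No pair of libraries agreed within sampling noise, the smallest reduced chi-square over 231 pairs being 24.7.

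The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 3 groups with the library pool (3 or 4, from the names of the deposited files) as an additive term. This left 13626 genes, 18 residual degrees of freedom and a biological coefficient of variation of 25.9%. The pools differed at 0 genes past an adjusted p of 0.05 by edgeR and at 602 with an unadjusted p under 0.05, where chance gives about 681. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and separately over the list alone. CPM are TMM-scaled. Totals of 15.3 to 31.6 M counts set the counting precision, which matters for genes near 1 CPM.

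The tests, the 38 gene lists (18 pathways and 20 marker sets), the named genes and most alternatives were fixed before the data were examined. Of the lists, 35 had at least 3 measured genes and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over lists within a comparison. Lists that the text does not name were not called in that comparison. Named genes were, per comparison, up to 8 rises and 8 falls among genes past the threshold with a mean log2 CPM of at least 1 and the same sign in both pools, up to 3 called members per list, the sterol genes HMGCS1, SQLE and INSIG1 and some others that are not reported here, and the 2 members with the smallest p of each interferon and inflammation list. Where fewer than 5 genes qualified, the 5 with the smallest adjusted p among genes with a symbol and a mean log2 CPM of at least 1 were named. Members past the threshold over their list alone, XBP1, PLXNC1, C1QB, ENSSSCG00000027665 and the single-library values were named after their values were seen.

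On counts simulated for the diet comparison from the real means and spreads of 13626 genes, the fit called 49.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 3-fold, with 12 unchanged genes called. With nothing changed it called 0 genes and 0 lists. A list shifted by 1.25-fold had a camera adjusted p of 5.28e-14, and 1 list that was not shifted was also called. These simulated genes vary independently, unlike real ones. The genes changed 1.5-fold (67), 2-fold (67) and 3-fold (66) were changed together, and all had a mean log2 CPM of at least 1. Where fewer genes change, the adjusted threshold is stricter, so these shares can overstate what the real comparison would detect. Alternatives covered the pool term, each pool alone, the groups in the fit, RLE scaling and total counts, DESeq2 1.42.0, limma with quality weights, 2 other filters, 2 surrogate variables (sva 3.50.0), a Y-linked covariate standing in for sex, estimation without robustness, a fold minimum of 1.5 and leaving out each library. List scores, the mean log2 CPM of members centred per gene, were compared by two-sided exact permutation tests over all splits.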

Results

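Jejunal mucosa, the absorptive lining of the middle small intestine, was profiled by RNA sequencing in Ossabaw pigs, a breed used as a model of diet-induced metabolic disease. The pigs ate a Western dietary pattern (WD, rich in butter fat, cholesterol and refined carbohydrate) or a heart healthy pattern (HHD, rich in unsaturated oils, whole grains, fruit, vegetables and fibre) for 6 months. Both patterns supplied 38% of energy as fat. Pigs on the heart healthy pattern also received fish oil capsules of 1000 mg. Atorvastatin, a cholesterol-lowering drug that inhibits cholesterol synthesis, was given at 20 mg per day for the first 3 months and 40 mg per day afterwards. The 22 libraries analysed here, each from a separate pig, formed 3 groups, with 7 pigs on the Western pattern with atorvastatin (WD_S), 8 on the heart healthy pattern with atorvastatin (HHD_S) and 7 on the heart healthy pattern alone (HHD). The pigs randomized in the study were 16 boars and 16 gilts. The labels do not give the sex of each pig, and the main model had no term for sex. The Western pattern without atorvastatin was not analysed here, so neither the effect of diet without the drug nor the interaction of diet and drug was estimated. The drug status of WD_S follows the sample labels, from which the series text differs. What each comparison with WD_S contrasts depends on those labels. Total unique exon read counts were between 15.3 and 31.6 M per library, and 13626 genes were tested.

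The comparison of WD_S with HHD_S asked how the dietary pattern differed in its association with jejunal expression while all pigs took atorvastatin. Genes of sterol efflux and the liver X receptor (LXR) programme, which exports excess sterol from cells, were higher as a group in WD_S. All 12 measured members had positive fold changes, with a median log2 fold change of 0.27 (camera adjusted p = 1.04e-08). Only 2 of them, ABCG1 and SCD, had an unadjusted p under 0.05 by edgeR. The group also passed with an estimated correlation between genes (adjusted p = 0.0198) and within each library pool (larger adjusted p = 3.03e-05). Markers of macrophages and dendritic cells were higher in the same comparison, with 12 of 13 positive and a median log2 fold change of 0.22 (camera adjusted p = 0.000595, and adjusted p = 0.360 with an estimated correlation). ABCG1, a cholesterol exporter on chromosome 13 (205561897 to 205628428, Sscrofa11.1, RefSeq gene span), stood at 31.9 ± 5.67 CPM in WD_S (SD, n = 7) and 19.1 ± 3.91 CPM in HHD_S (SD, n = 8). Its log2 fold change was 0.74 (SE 0.128), with an edgeR adjusted p of 0.0641 over all genes and 9.37e-05 when adjusted over the list alone. SCD, which makes monounsaturated fatty acids (chromosome 14, 111461560 to 111478033), stood at 73.6 ± 36.9 CPM against 25.7 ± 19.4 CPM, a log2 fold change of 1.40 (SE 0.423, adjusted p = 0.0207 over the list alone).

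Genes of cholesterol synthesis and its regulation, which are switched on by the transcription factor SREBP2 when cells are short of sterol, were lower as a group in WD_S. Of 25 measured members, 22 had negative fold changes, with a median log2 fold change of -0.20 (camera adjusted p = 3.96e-06, and adjusted p = 0.360 with an estimated correlation). Within library pool 4 alone the list was not called (median -0.10, adjusted p = 0.119). SQLE, which carries out an early oxygen-requiring step of sterol synthesis (chromosome 4, 14669789 to 14700152), stood at 4.49 ± 2.28 CPM in WD_S (SD, n = 7) and 12.2 ± 6.03 CPM in HHD_S (SD, n = 8). Its log2 fold change was -1.38 (SE 0.315), with an edgeR adjusted p of 0.611 over all genes and 0.00607 over the list alone. It was the single member past the threshold over the list alone. HMGCS1, an early enzyme of sterol synthesis, had a log2 fold change of -0.54 (SE 0.224). INSIG1, which retains the SREBP proteins in the endoplasmic reticulum, had a value of 0.39 (SE 0.320). Neither HMGCS1 nor INSIG1 passed the test.

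**Figure D1:**
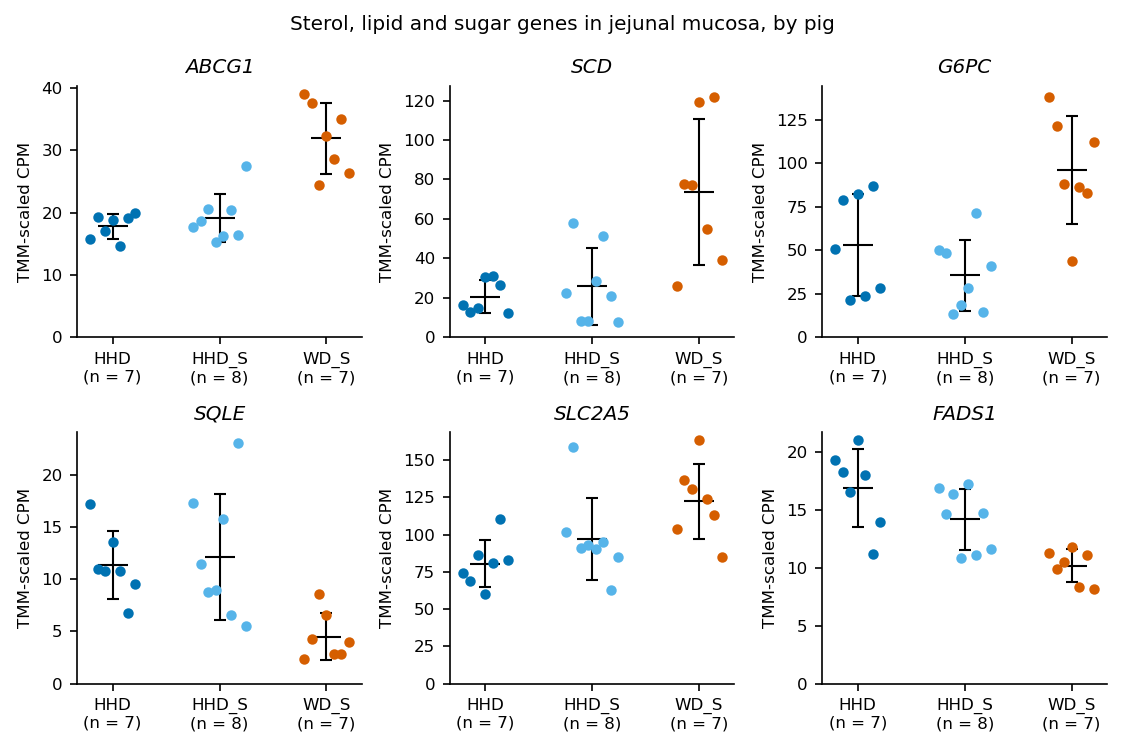
TMM-scaled CPM of 6 genes in each pig, by group. Points are pigs, horizontal bars are group means and whiskers are SD. ABCG1 ran from 24.4 to 39.1 CPM in WD_S, from 15.4 to 27.6 CPM in HHD_S and from 14.6 to 20.0 CPM in HHD.

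Genes of sugar digestion and fructose metabolism were also higher as a group in WD_S, with 14 of 17 members positive and a median log2 fold change of 0.28 (camera adjusted p = 1.40e-06, and adjusted p = 0.183 with an estimated correlation). G6PC, the catalytic subunit of glucose-6-phosphatase (chromosome 12, 19965885 to 19975783), stood at 96.0 ± 30.9 CPM in WD_S (SD, n = 7) and 35.5 ± 20.5 CPM in HHD_S (SD, n = 8), with an adjusted p of 0.0226 over the list alone. The fatty acid synthesis and desaturation list had no call (camera adjusted p = 0.158, median -0.03 and mean 0.12 in opposite directions). Within it FADS1, a desaturase of polyunsaturated fatty acid synthesis, had a log2 fold change of -0.48 (SE 0.144, adjusted p = 0.0258 over the list alone). SCD belongs to this list as well as to the sterol efflux list, and passed over it in the opposite direction (log2 fold change 1.40, adjusted p = 0.0258). Bile acid genes were called higher (camera adjusted p = 0.0426, and adjusted p = 0.360 with an estimated correlation), with NR0B2, a repressor induced by the bile acid receptor, at a log2 fold change of 0.64 (SE 0.194, adjusted p = 0.0131 over the list alone). That of NR0B2 was 1.10 within library pool 3 and 0.14 within pool 4. The call of the bile acid list was kept in 19 of 39 alternatives (adjusted p up to 0.602). It was lost in 10 of 22 fits without 1 library, those without WD_S 1, 2, 3 or 7, HHD 1 or 6, or HHD_S 1, 2, 3 or 5 (adjusted p up to 0.213, without HHD_S 5). FABP6, an ileal bile acid binding protein, had a log2 fold change of 3.95 (SE 1.12) that rested on WD_S 1, which had 26.1 CPM, and was 1.68 without it.

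The macrophage and dendritic cell markers were not called within library pool 4 alone (adjusted p = 0.214). Tuft cell (adjusted p = 0.0161) and mast cell and eosinophil markers (adjusted p = 0.0299) were higher, and T and natural killer cell markers were lower (adjusted p = 0.0342). Endoplasmic reticulum stress genes were called higher (adjusted p = 0.0336) with a median of 0.06. With an estimated correlation the adjusted p was 0.360 for the macrophage, tuft and mast cell lists and 0.674 for the T cell and stress lists. The macrophage call was kept without each library in turn, and the other 4 calls were not. The tuft cell call was lost without WD_S 1 or HHD_S 6 (adjusted p up to 0.105), and the mast cell call without WD_S 1 or 3 or HHD_S 3, 6 or 7 (up to 0.149), with a median of -0.14 in pool 4 alone. The T cell call was lost without WD_S 1, 5 or 6 or HHD_S 3, 5 or 7 (up to 0.595), and the stress call without WD_S 1, 5 or 7, HHD 5, or HHD_S 1, 2, 3, 4 or 8 (up to 0.192). The type I interferon (adjusted p = 0.248), interferon gamma (adjusted p = 0.951) and inflammation lists (adjusted p = 0.147) were not called. Without WD_S 7 the type I interferon list was called lower in WD_S (median -0.36, adjusted p = 0.0402), and without WD_S 6, HHD_S 7 or HHD_S 8 it was called higher (median up to 0.46, adjusted p down to 0.000238, without HHD_S 7). The members of these lists with the smallest p were IFITM3 and TRIM25, TAPBP and SLA-DQB1, and CCL5 and ICAM1, with edgeR adjusted p of 0.9995 each. The enterocyte list was not called (adjusted p = 0.184), and HHD_S 3 and HHD_S 8 had the lowest enterocyte scores of their group, at -0.98 and -0.53.

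No single gene passed the threshold in the diet comparison. edgeR's quasi-likelihood test called 0 of 13626 genes at an adjusted p of 0.05, with 398 genes at an unadjusted p under 0.05. Chance alone gives about 681 genes at that level. DESeq2 called 4 genes, which were SQLE, APOD, ABCG1 and ENSSSCG00000027665, and limma with quality weights called 1, ABCG1. By edgeR ENSSSCG00000027665, a gene without a symbol, had the same adjusted p as ABCG1 (0.0641), with a log2 fold change of 1.32 (SE 0.231). Among genes with a symbol, S100A1, SQLE, APOD and LRRC25 came next by p, each with an adjusted p of 0.611, which the gene after them, PLXNC1, shared. APOD, an apolipoprotein, stood at 34.2 ± 21.4 CPM in WD_S (SD, n = 7) and 12.4 ± 5.74 CPM in HHD_S (SD, n = 8). S100A1 and LRRC25 had log2 fold changes of -0.63 (SE 0.145) and 0.67 (SE 0.156).

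**Figure D2:**
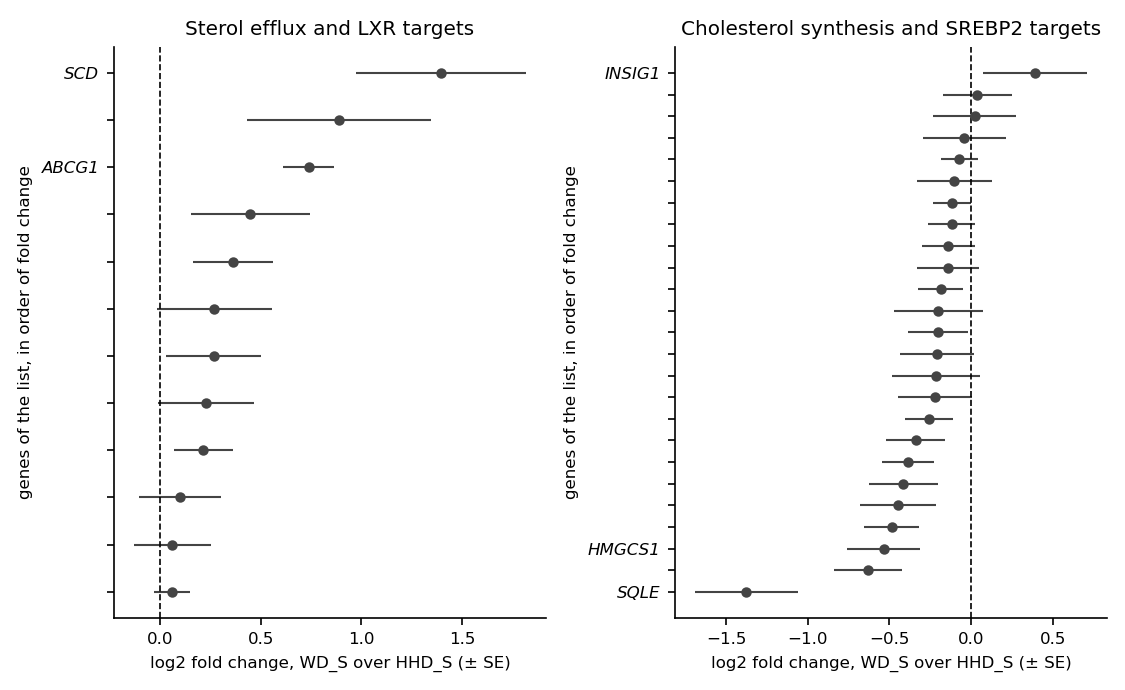
Fitted log2 fold change of WD_S over HHD_S, with its SE, for each measured gene of 2 lists, with the genes named in the text labelled. All 12 sterol efflux and LXR genes lie above 0, and 22 of 25 cholesterol synthesis genes lie below 0.

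The comparison of HHD_S with HHD asked how atorvastatin was associated with expression under the heart healthy pattern. No sterol gene passed the test. SQLE stood at 12.2 ± 6.03 CPM with atorvastatin (SD, n = 8) and 11.4 ± 3.27 CPM without (SD, n = 7), a log2 fold change of 0.09 (SE 0.295). HMGCS1 stood at 68.0 ± 28.4 CPM with atorvastatin (SD, n = 8) and 68.9 ± 18.2 CPM without (SD, n = 7), a log2 fold change of -0.02 (SE 0.215). That of INSIG1 was -0.26 (SE 0.327), and these genes each had an edgeR adjusted p of 0.9993. The cholesterol synthesis list (camera adjusted p = 0.239) and the sterol efflux list (adjusted p = 0.440, median 0.0057 and mean -0.02 in opposite directions) were not called.

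Genes of endoplasmic reticulum stress and protein folding were lower as a group with atorvastatin, with 18 of 20 negative and a median log2 fold change of -0.27 (camera adjusted p = 1.74e-08, and adjusted p = 0.552 with an estimated correlation). Within library pool 4 alone the list was not called (median -0.11, adjusted p = 0.762). None of its members passed over the list alone, and the smallest p belonged to XBP1, a transcription factor of the unfolded protein response, at -0.32 (SE 0.132). Goblet cell markers moved in the same direction, with 8 of 8 negative (camera adjusted p = 0.000131, and adjusted p = 0.552 with an estimated correlation). So did plasma cell markers, with 9 of 9 negative (camera adjusted p = 0.00340, and adjusted p = 0.704 with an estimated correlation), although their median was 0.14 within pool 4 alone. XBP1 belongs to both the stress list and the plasma cell list, so these 2 lists are not separate. Fibroblast (adjusted p = 0.00787), endothelial (adjusted p = 0.00867), smooth muscle (adjusted p = 0.0356), cell division (adjusted p = 0.0394) and fatty acid synthesis lists (adjusted p = 0.0107) were also called lower. With an estimated correlation the adjusted p was 0.704 for the endothelial and fatty acid lists, 0.72 for fibroblasts and 0.750 for smooth muscle and cell division. For cell division, atorvastatin under HHD had the opposite sign within pool 4 alone (median 0.23, adjusted p = 0.0358). The cell division list kept its call and direction in 17 of 39 alternatives, smooth muscle in 20, fatty acid synthesis in 28, and the fibroblast and endothelial lists in 31 each. Leaving out 1 library ended the cell division call in 12 of 22 fits, those without WD_S 4 or 7, HHD 1, 2, 3 or 7, or HHD_S 1, 2, 3, 4, 6 or 8 (adjusted p up to 0.667 and median 0.0037, without HHD 7). It ended the smooth muscle call in 10, those without WD_S 3 or 4, HHD 1, 2, 3, 4 or 6, or HHD_S 4, 7 or 8 (up to 0.511, without HHD_S 8). The fatty acid call was lost without HHD 1 or 4 or HHD_S 4 or 8 (up to 0.208), the fibroblast call without HHD 2, 3 or 4 or HHD_S 7 or 8 (up to 0.126), and the endothelial call without HHD 2 or 4 or HHD_S 4 or 7 (up to 0.208). Circadian clock genes were higher, with 14 of 19 positive (camera adjusted p = 0.000368, and adjusted p = 0.621 with an estimated correlation), and were not called within library pool 4 alone (adjusted p = 0.164). TEF, a clock output transcription factor, stood at 11.6 ± 3.46 CPM with atorvastatin (SD, n = 8) and 6.33 ± 2.39 CPM without (SD, n = 7), with an adjusted p of 0.0258 over the list alone. SH2D6, a tuft cell marker, had a log2 fold change of 0.54 (SE 0.184, adjusted p = 0.0489 over the list alone), while the tuft cell list was not called (adjusted p = 0.880, median -0.03 and mean 0.03).

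The type I interferon list was called higher with atorvastatin (camera adjusted p = 0.00867, and adjusted p = 0.750 with an estimated correlation), and without HHD_S 7 its median log2 fold change was -0.18 (adjusted p = 0.891). The call was also lost without HHD 2, 3, 4 or 5 or HHD_S 8 (adjusted p up to 0.254, without HHD 5). The interferon gamma (adjusted p = 0.604, and 0.0467 and lower without HHD_S 7) and inflammation lists (adjusted p = 0.152) were not called. IFI6, USP18, CIITA, WARS, DUOX2 and CXCL14, the members of these lists with the smallest p, each had an edgeR adjusted p of 0.9993. edgeR called 0 of 13626 genes, with 247 at an unadjusted p under 0.05, where chance gives about 681. DESeq2 called FOLH1B and limma called 0. The fold change of FOLH1B (log2 -3.93, SE 0.966) rested on HHD 5 and HHD 6, at 59.1 and 94.7 CPM, and was -2.02 on the log2 scale without HHD 6. Its value is uncertain, since near-identical copies can share its reads. Among genes with a symbol and a mean log2 CPM of at least 1, those with the smallest p after FOLH1B were PDZD9, ROBO3, GPATCH2 and TEF, with log2 fold changes of 0.66 (SE 0.171), 0.88 (SE 0.239), 0.65 (SE 0.178) and 0.88 (SE 0.239). No call of a list in this comparison held with an estimated correlation.

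The comparison of WD_S with HHD differed in diet and drug at once and was the sum of the other 2 contrasts. It shares its libraries with both and is not independent of them. ABCG1 rose and was the 1 gene past the threshold, at 31.9 ± 5.67 CPM in WD_S (SD, n = 7) and 17.8 ± 2.02 CPM in HHD (SD, n = 7). Its log2 fold change was 0.84 (SE 0.136, edgeR adjusted p = 0.0410), with 0.89 within library pool 3 and 0.88 within pool 4, and it passed in neither pool alone (adjusted p = 0.994 and 0.9998). In fits without 1 library its adjusted p ran from 0.00325 to 0.280 and the call was lost in 17 of 22, all except those without WD_S 3, WD_S 7, HHD_S 4, HHD_S 7 or HHD_S 8. With total counts in place of TMM scaling the adjusted p was 0.779.

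The sterol efflux list was higher in WD_S than in HHD, with 10 of 12 positive (camera adjusted p = 9.26e-06, and adjusted p = 0.132 with an estimated correlation), the macrophage and dendritic cell markers were not called (9 of 13 positive, adjusted p = 0.206), and SCD had a log2 fold change of 1.71 (SE 0.445, adjusted p = 0.00558 over the list alone). The cholesterol synthesis list was lower, with 20 of 25 negative and a median of -0.24 (camera adjusted p = 8.00e-08, and adjusted p = 0.333 with an estimated correlation). SQLE stood at 4.49 ± 2.28 CPM in WD_S (SD, n = 7) and 11.4 ± 3.27 CPM in HHD (SD, n = 7), a log2 fold change of -1.28 (SE 0.321, adjusted p = 0.0153 over the list alone). HMGCS1 and INSIG1 had log2 fold changes of -0.55 (SE 0.230) and 0.13 (SE 0.342) and did not pass. Sugar digestion and fructose genes were higher, with 15 of 17 positive (camera adjusted p = 7.15e-05, and adjusted p = 0.333 with an estimated correlation), among them the fructose transporter SLC2A5 at 0.65 (SE 0.172, adjusted p = 0.0167 over the list alone).

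FADS1 stood at 10.2 ± 1.43 CPM in WD_S (SD, n = 7) and 16.9 ± 3.35 CPM in HHD (SD, n = 7), with an edgeR adjusted p of 0.414 over all genes and 0.000912 over the fatty acid synthesis list alone, and DESeq2 called it. SCD passed over the same list in the opposite direction (log2 fold change 1.71, adjusted p = 0.00698), and the list itself was not called (camera adjusted p = 0.653, median -0.05 and mean 0.05). CYP1B1, a target of the aryl hydrocarbon receptor, had a log2 fold change of -1.48 (SE 0.349), and its list was not called (camera adjusted p = 0.102). RELT had 0.63 (SE 0.159) and NR0B2 0.71 (SE 0.203). SLC7A11, a cystine transporter, was near the detection floor at 0.439 and 1.09 CPM. Enteroendocrine (adjusted p = 0.0117) and tuft cell markers (adjusted p = 0.0117) were higher and endoplasmic reticulum stress genes lower (adjusted p = 0.0215) by camera, with adjusted p of 0.816, 0.333 and 0.83 with an estimated correlation. The enteroendocrine call was lost without WD_S 3, HHD 5 or HHD 7 (adjusted p up to 0.195), the tuft cell call without WD_S 1 or HHD 7 (up to 0.117), and the stress call without WD_S 2, 3 or 6, HHD 1, 4 or 7, or HHD_S 5 (up to 0.137). None of these 3 lists was called in the same direction within pool 4 alone. The type I interferon list was called higher (camera adjusted p = 0.000744, and adjusted p = 0.83 with an estimated correlation), with an adjusted p of 0.621 without WD_S 7. For the type I interferon response, diet and atorvastatin together had an adjusted p of 0.0702 without HHD 5. The interferon gamma (adjusted p = 0.678) and inflammation lists (adjusted p = 0.968, test upward with a median of -0.04) were not called. RSAD2, TRIM25, CIITA, PSMB10, DUOX2 and RELB had edgeR adjusted p of 0.9997 each. DESeq2 called 2 genes, FADS1 and ABCG1, and limma with quality weights called 1, ABCG1. By edgeR 465 genes had an unadjusted p under 0.05, where chance gives about 681.

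**Figure D3:**
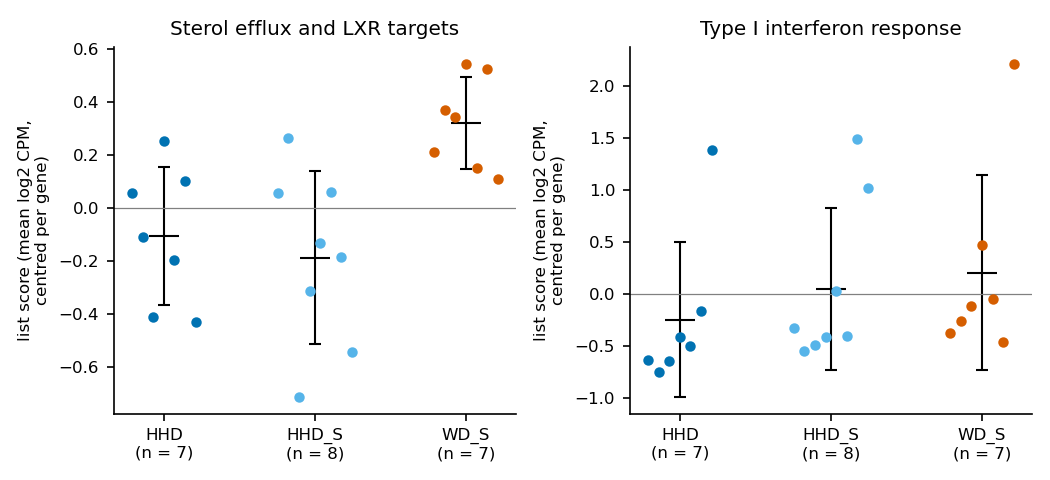
Mean log2 CPM of the members of 2 lists in each pig, centred per gene over all 22 libraries, by group. Points are pigs, bars are means and whiskers are SD. The highest type I interferon score of each group belonged to WD_S 7 (2.21), HHD_S 7 (1.49) and HHD 7 (1.38).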

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

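The tests of the library pool, of HHD_S 3 and 8, of WD_S 7, of the title number and of tissue position were chosen after the results were seen, and the reading of the tissue position test was changed from excluded to undecided at that stage. That of the title number was changed to undecided and then back to excluded, as a linear trend only. This last reading rests on the nearly equal mean numbers of WD_S and HHD, since the covariate fit could hardly have lost the call. The rule for reading the counts over 100 splits of the libraries was written beforehand. These splits were not among the tests fixed before the data were examined. The lists singled out for them include the one with the smallest camera p of each comparison. In 183 groups of values examined for a library far from the rest, 29 values stood apart, where chance gives about 1 in 20. That share holds for independent, normally distributed values. Many of these values are CPM without a log scale, of genes high in the same pigs, so the number is not a test against chance.

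Sterol efflux and LXR genes were higher in WD_S than in HHD_S. Of 100 splits of these 15 libraries, 1 gave a camera p as small, the real one (2.97e-10, smallest other 3.16e-07). This list had the smallest camera p of the comparison, and other splits gave other lists smaller ones (type I interferon down to 7.2e-42 by camera). The count therefore does not by itself argue against chance. The list remained past the threshold without HHD_S 3 and 8 (adjusted p = 7.41e-06) and within each library pool (larger adjusted p = 3.03e-05), which argues against those libraries or the pools as the whole cause. HHD_S 3 and 8 had the lowest scores of their group for this list (-0.71 and -0.54), so a part of the difference may rest on them. The score test below used all 15 libraries and was not run without them. A two-sided exact permutation test of the list scores gave p = 0.00264, with 7 of 7 WD_S pigs above the HHD_S mean. Adjusted over 35 lists its p was 0.0925, so chance was not excluded once all lists were counted. Markers of macrophages and dendritic cells, a list that shares no gene with this one, were also higher (12 of 13 positive, camera adjusted p = 0.000595, and adjusted p = 0.360 with an estimated correlation), with C1QB, the most abundant of them, at 333.4 ± 84.6 CPM in WD_S (SD, n = 7) and 299.9 ± 69.5 CPM in HHD_S (SD, n = 8). A larger share of those cells and the diets themselves, which differ in many components at once, both stay open, and no test here separated them.

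The cholesterol synthesis list was less clear. Of 100 splits, 12 gave a camera p as small in the diet comparison (real 3.4e-07, smallest other 2.20e-14), so chance could not be excluded there. For WD_S against HHD 3 did (real 2.29e-09, smallest other 7.47e-10). The list had the smallest camera p of that comparison, so this count does not by itself argue against chance. Two-sided exact permutation tests of its scores gave p = 0.146 (adjusted 0.560) in the diet comparison and 0.0122 (adjusted 0.143) for WD_S against HHD. For sterol efflux in WD_S against HHD 1 split of 100 did, the real one (5.29e-07, smallest other 4.86e-05), and for endoplasmic reticulum stress under atorvastatin 1 did, the real one (4.96e-10, smallest other 5.63e-10). The exact permutation p of these list scores were 0.00408 (adjusted 0.143) and 0.0988 (adjusted 0.882), so for endoplasmic reticulum stress the score test did not exclude chance. The split counts were not adjusted for the number of lists. Adjusted over lists, none of these score tests excluded chance. Other lists had split counts as low, such as sugar digestion in the diet comparison and goblet cells under atorvastatin (2 of 100 each). The numbers of called lists were not unusual: 45 of 100 splits called at least 9 lists in the diet comparison (highest other 16), 44 at least 10 for atorvastatin (highest other 17) and 60 at least 7 for WD_S against HHD (highest other 15). Genes at an unadjusted p under 0.05 were as many as the real 398, 247 and 465 in 65, 90 and 45 of 100 splits in the diet comparison, for atorvastatin and for WD_S against HHD (medians of the other splits 546, 720 and 427), so chance could not be excluded for these counts. A count of 0 called genes, as in the diet and atorvastatin comparisons, is reached by all 100 splits by definition and says nothing about chance (highest other 2 and 21). For WD_S against HHD, 3 splits of 100 called at least 1 gene, and 1 of these called 282. Counts of 282 and 21 can point to a structure of the samples other than the groups, but what these splits separate was not tested.

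The type I interferon list, called higher in WD_S than in HHD, may rest on single pigs. Its camera adjusted p was 0.000744, with an adjusted p of 0.83 with an estimated correlation and 0.621 by camera without WD_S 7, and 46 of 100 splits gave a camera p as small (real 8.51e-05, smallest other 4.50e-35). With the number in the sample title as a covariate the camera adjusted p was 3.14e-18 (1.72e-24 to 0.942 over the alternatives). The mean number was 2341 ± 12.2 in WD_S (SD, n = 7) and 2341.1 ± 12.2 in HHD (SD, n = 7). With means this close, a linear trend with that number could account for little of the difference between the groups. The covariate fit could therefore hardly have lost the call, and it adds nothing to this. Relations other than a linear one were not tested. No biological explanation was tested.

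The list scores of WD_S 7 (2.21) and HHD 7 (1.38) stood apart from their groups, as did the interferon gamma score of HHD 7 (1.11). In WD_S 7 the CPM of IFI6 (382.1), IFITM3 (59.8), RSAD2 (524.7), USP18 (106.6) and WARS (117.0) stood apart. In HHD 7 those of IFI6 (99.9), IFITM3 (56.8), PSMB10 (278), RSAD2 (93.3), TRIM25 (75.1), USP18 (43.5), WARS (217.3) and SLC7A11 (3.02) did, and in HHD_S 7 those of PSMB10 (234.2), TRIM25 (78.4) and WARS (117.2).

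FABP6 stood at 26.1 CPM in WD_S 1, where the other WD_S pigs had 1.77 or less, and the bile acid score of that library was 1.01. Tissue from a more distal position is a candidate explanation. The other genes of the ileum list lay a median of 0.083 log2 units from the other 21 libraries, but most of them are abundant in every library and could hide a small share. SLC10A2, the ileal bile acid transporter, was at 7.97 CPM against a median of 1.28 and a highest value of 7.76 in the others, so the explanation cannot be told apart from a difference between pigs. No biological explanation was tested.

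Single values also stood apart for ABCG1 in HHD_S 8 (27.6 CPM), FABP6 (0.817 CPM) and SLC7A11 (1.27 CPM) in HHD_S 5, INSIG1 in HHD 1 (235.3 CPM), SLC2A5 in HHD_S 2 (159 CPM) and TEF in HHD 5 (11.3 CPM). The circadian clock score of HHD_S 7 was -0.43 and the endoplasmic reticulum stress score of HHD 5 was -0.49.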

How the results depend on the processing

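The title number, the removal of HHD_S 3 and 8 and the removal of the 4 libraries with the highest type I interferon scores were chosen after seeing the data, the last by a measured value. The sterol efflux list in the diet comparison kept its direction and call in 39 of 39 alternatives, with adjusted p up to 0.0420. Cholesterol synthesis kept its call in 36 of 39, losing it within pool 4 alone (adjusted p = 0.119) and with both other list tests. Among single genes and lists, 3221 values kept direction and side of the threshold, 217 lost their call, 28 gained one, 78 uncalled values changed sign and 9 turned direction with a call on either side. Of the single genes, only ABCG1 in WD_S against HHD was called in the main fit, so an uncalled gene that stayed uncalled says little. That call was kept in 19 of 40 alternatives and lost in 21.

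For genes past the threshold in the diet comparison (0 as reported), the count was 2 without the pool term, 4 by DESeq2, 1 by limma with quality weights, 2 with surrogate variables, 1 with the Y-linked covariate, 1 without HHD_S 3 and 8, 1 without the 4 interferon-high libraries, 2 with the title number and 2 with the title number and Y-linked covariate. Without 1 library it ran from 0 to 2, the 2 being without WD_S 7. For atorvastatin (0 as reported) DESeq2 gave 1, and leaving out 1 library gave 0 each time. For WD_S against HHD (1 as reported) it was 0 in pool 3 alone, 0 in pool 4 alone, 0 with total counts, 0 with a fold minimum of 1.5, 2 by DESeq2, 2 with the title number and 2 with the title number and Y-linked covariate, and 0 to 1 without 1 library. The call of ABCG1 was kept without WD_S 3, WD_S 7, HHD_S 4, HHD_S 7 or HHD_S 8. Single pools hold fewer pigs. For the other changes the cause was not tested.

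For lists in the diet comparison (9 as reported) the count was 1 with an estimated correlation, 1 with fry, 4 in pool 4 alone and 17 with total counts, and 7 to 15 without 1 library (15 without WD_S 7, 14 without HHD 7). For atorvastatin (10) it was 0 with an estimated correlation, 0 with fry and 5 to 12 without 1 library (5 without HHD 4). For WD_S against HHD (7) it was 0 with an estimated correlation, 0 with fry, 13 without the pool term and 5 to 10 without 1 library. With fry or an estimated correlation the test itself allows for correlated genes.

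Directions turned for the type I interferon list, at a median log2 fold change of -0.44 in pool 3 and -0.36 without WD_S 7 in the diet comparison (leave-outs up to 0.46), -0.18 without HHD_S 7 for atorvastatin (leave-outs up to 0.61), and -0.35 in pool 3 for WD_S against HHD. In pool 4 they turned for mast cells (-0.14) in the diet comparison, for cell division (0.23) and plasma cells (0.14) under atorvastatin, and for endoplasmic reticulum stress (-0.036, by its test rather than its median) in WD_S against HHD. With surrogate variables interferon gamma was 0.11 in WD_S against HHD. The cause was not tested. TMM, RLE and total counts moved the median gene by under 0.05 on the log2 scale. Total gene reads and pseudocounts were not run because the files hold unique exon counts. No paired analysis was possible because the replicate numbers only name the pigs. Depth limits genes near 1 CPM, such as SLC7A11.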

Other observations

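The macrophage and dendritic cell score was 0.11 ± 0.24 in WD_S (SD, n = 7) and -0.12 ± 0.25 in HHD_S (SD, n = 8), with a two-sided exact permutation p of 0.0971 and an adjusted p of 0.560. For tuft cells the score was 0.19 ± 0.18 in WD_S and -0.09 ± 0.28 in HHD_S, with an exact permutation p of 0.0508 and an adjusted p of 0.548. The aryl hydrocarbon receptor list scored -0.33 ± 0.44 in WD_S (SD, n = 7) and 0.23 ± 0.42 in HHD (SD, n = 7), with 0 of 7 WD_S pigs above the HHD mean (two-sided exact permutation p = 0.0344, adjusted p = 0.241). No list passed an adjusted p of 0.05 in these exact tests, the smallest being 0.0925 for sterol efflux.

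The removal of libraries by interferon score and the title number were looked at only after the scores were seen. The 4 highest type I interferon scores over all 22 libraries were those of WD_S 7, HHD_S 7, HHD 7 and HHD_S 8, at 2.21, 1.49, 1.38 and 1.02. Their sample titles carry the numbers 2362, 2358, 2357 and 2366, which are the 4 highest in the series. HHD 6, numbered 2356, had a score of -0.17. The labels do not say what the number counts, and the scores were not tested against it.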
